A study of Mus musculus with 3 samples.

How the data were processed

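Total RNA of whole mouse skin was extracted at 3 times, day 0 without drug and days 1 and 2 after cyclophosphamide, and 1 library was made per time. Per the labels' protocols, polyadenylated RNA was bound to oligo(dT) beads and copied into double-stranded cDNA, which was cut at CATG with NlaIII. MmeI then released tags of 21 bases (CATG and the 17 bases after it), which were amplified by PCR and sequenced on an Illumina Genome Analyzer. Per the series design text, tags were annotated against a mouse gene database of the sequencing centre. The aligner, the mismatches allowed, the UniGene build and the genome build are not given in the sources used here.

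Each deposited table lists UniGene clusters with, per the file headers, a raw count of tags per cluster, and with each tag mapped to it, that tag's copy number and the number of its CATG site from the 3' end. In every cluster the copy numbers sum to the deposited count (0 exceptions). The deposited TPM values are the same counts per 1000000 of all tags the authors kept. Dividing counts by TPM gave 6030092, 6070061 and 5666061 kept tags at days 0, 1 and 2, of which the tables hold 45.3%, 47.1% and 46.5%. The smallest copy number listed is 2, so a gene that is not listed in a library need not have had 0 tags. Such a gene was tested as 0 tags, and its value with the pseudocount entered list medians and their intervals, but no ratio is printed for it and none is given as a limit. A sample group was taken from the treatment and time labels, and the labels give every group the replicate number 1.

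Counts were analysed as deposited, by cluster. Names came from an exact match of the tags to GENCODE mouse release M21 transcripts (GRCm38). A tag was placed wherever CATG and its next 17 bases occur on the sense strand, and a cluster took the symbol of the gene that held at least 80% of its matched tags and 50% of all its tags. Of 20595 clusters in any table, 15153 were named this way and 616 more by tags that also occur in pseudogenes or paralogs. A further 203 were named by their RefSeq accession alone, and 4623, with 4.9% of tags, stayed unnamed and entered the tests without a symbol. Of the clusters named by tags that also carry a RefSeq accession, 5400 had the same symbol by both routes and 90 another. Tags that match a transcript of 1 gene made up 80.63%, 82.89% and 82.31% of the libraries, and those that match several genes 12.37%, 9.62% and 9.29%. Genes named through such shared tags, among them haemoglobins, many ribosomal proteins and Krtap10-4, are uncertain in that the tags cannot separate the copies. Coordinates and exons of single tags are from that match, counted from 1.

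Library sizes were scaled by edgeR's TMM over the 3 libraries (factors 1.03, 0.94 and 1.03), and 13812 clusters with 15 or more tags summed over the libraries were tested, of which 11343 were named genes. edgeR's quasi-likelihood test needs replicates and could not be used. Instead, a two-sided exact conditional binomial test was applied to the reads of 2 libraries, with Benjamini-Hochberg adjustment over all clusters tested, and a gene was called at an adjusted p of 0.001 or less and a ratio of 2 or more either way. Levels are given as CPM, counts per 1000000 after this scaling. Log2 ratios carry a pseudocount of 0.5 tags scaled to library size. Intervals of single ratios are exact (Clopper-Pearson) at 95%, those of list medians are order-statistic intervals over members at 95%, and those of shares of a library are Wilson intervals. The intervals of single ratios and of shares cover counting error only, while those of list medians cover the spread over members. PCR copies cannot be told from separate molecules, and none of these intervals takes them into account. A median was also placed among those of 10000 random lists of the same size matched in 20 bins of mean expression.

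On simulated libraries with the real means and sizes, 200 of the 13812 clusters were changed in each comparison, 50 at each of 4 folds. For day 1 over day 0, the test called 0 of 50 at 1.5-fold, 20 at 2.5-fold, 33 at 4-fold and 43 at 8-fold. For day 2 over day 0 it called 0, 20, 35 and 37, and for day 2 over day 1 it called 1, 23, 36 and 44. Of those changed 4-fold at 20 CPM or more, it called 24 of 24, 21 of 21 and 22 of 22. It called 0 unchanged clusters and 0 in the wrong direction. The simulated counts varied by Poisson counting error alone, without variation between animals, PCR copies or CATG sites. These counts of 0 therefore do not measure false calls in the real libraries. Genes below 20 CPM are often missed even with counting error alone.

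The text names, for each comparison, the 8 genes called higher and the 8 called lower with the largest ratios among those at 20 CPM or more in the higher library, leaving out clone and predicted-gene names. From each list described it takes up to 4 members with the largest ratios at that level, then a fixed set of genes wherever measured, and the 5 genes with the most tags in each library; a selection of these is printed. The signs and correlation of ratios at both days used 100 simulations of unchanged libraries against the same day 0 library, again with Poisson counting error alone.

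Alternatives fixed beforehand were scaling by all kept tags, by tags assigned to genes, by DESeq2 size factors and by tags outside hair and muscle genes; filters of 1 and 60 tags; the 3'-most site alone; no fold minimum and a minimum of 4; a pseudocount of 5; edgeR's exact test with an assumed coefficient of variation of 0.2 or 0.4 at an adjusted p of 0.05 and no fold minimum; hair totals with tags shared within a list; and antisense tags of 1 gene. Counting tags that match 1 reference gene exactly was added after the data were seen. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Functional annotation columns of the tables were left out because they carry no measurement, and the 41 lists are described in the results or in the closing section.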

Results

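Whole skin of male C57BL/6 mice, 2 months old, was profiled by digital gene expression, in which each polyadenylated transcript is counted through a 21-base tag that starts at a CATG site cut by NlaIII. Cyclophosphamide, an alkylating anticancer drug that damages dividing cells, was injected into the peritoneum at 150 mg/kg, 9 days after depilation, which starts a growth phase of the hair follicles. The series design text gives mg/kg, while the sample labels write the dose per km. There were 3 libraries, 1 in each of 3 groups: untreated skin (day 0), skin at day 1 and skin at day 2 after the drug. The treated skins were thus also 1 and 2 days further into induced hair growth than skin taken on the day of injection, and no untreated skin of those days was profiled, so each comparison joins the drug with that time. How many mice stand behind each library is not given in the sources used here. The tables held 2731787, 2859653 and 2636804 tags at days 0, 1 and 2, assigned to 17831, 17308 and 17829 UniGene clusters.

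Levels below are counts of tags per 1000000 (CPM) after scaling by the trimmed mean of M values (TMM). Where the log2 ratio of a gene is printed with a 95% interval, that interval covers counting error only. Many ratios of genes are printed without one. The 95% interval of a list's median is taken over its members. Without a second library in any group, no difference between days has a replicate check. A gene was called higher or lower when an exact conditional binomial test of the reads of 2 libraries, Benjamini-Hochberg adjusted over 13812 clusters, gave an adjusted p of 0.001 or less at a change of 2-fold or more. This test compares the 2 libraries, not the conditions, and PCR copies of a tag are not independent molecules. The tests, the 41 gene lists, the rule for the genes named and all but 1 of the alternatives were fixed before the data were examined, and each list was read in 3 comparisons.

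The day 1 and day 0 libraries answer what differed in skin 1 day after the drug. Interferon-stimulated genes, a set of antiviral genes switched on by interferons, were higher at day 1. Of 18 measured members 10 rose and 0 fell (12 and 0 when adjusted over the list alone). The median log2 ratio was 1.87 (1.24 to 2.22), at percentile 100 of 10000 random lists of the same size matched on mean expression. Ifit3, an interferon-induced protein that binds viral RNA complexes, on chromosome 19 (34583531 to 34588731, GRCm38), rose from 7.82 to 86.63 CPM. Its log2 ratio was 3.44 (2.84 to 4.17), with an adjusted p of 1.2e-45 in the exact test. Ifit1 of the same family rose by 2.79 (2.14 to 3.58), the ubiquitin-like modifier Isg15 by 2.48 (2.04 to 2.97) and Ifih1, a sensor of double-stranded RNA, by 2.21 (1.51 to 3.04).

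The gene with the largest ratio among those at 20 CPM or more was Mgmt, which removes alkyl groups from guanine in DNA. It rose from 5 tags at day 0 to 99 at day 1, a log2 ratio of 4.24 (3.10 to 6.03). Most of its tags (86 at day 1) were CATGAGGGCATCCCGACCGGA, on chromosome 7 (137127984 to 137128004), in the coding part of exon 5 of 5 and 2262 bases from the annotated transcript end. Only 4.4% of Mgmt tags lay at the 3'-most site. Mgmt was the 1 of 31 measured DNA repair genes that rose, also when adjusted over the list alone. The list's median was 0.06 (-0.14 to 0.34), with a sign that depended on the scaling. Among 34 measured p53 target genes 2 rose and 0 fell, the same numbers as when adjusted over the list alone. The median was 0.28 (0.01 to 0.72), at percentile 99.5 of random lists, with 24 of 34 ratios positive. The 2 called higher were Ephx1, a microsomal epoxide hydrolase, at 1.82 (1.64 to 2.02), and Tnfrsf10b, a death receptor, at 1.53 (0.87 to 2.27). The p53 targets Cdkn1a, a cell cycle inhibitor, and Mdm2, the ligase that degrades p53, were not called, at -0.03 (-0.46 to 0.40) and -0.33 (-0.73 to 0.07). Tags at the 3'-most site of Cdkn1a alone gave 2.22.

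Transcripts of the growing follicle moved in several ways at day 1. Shh, the Hedgehog ligand made by hair matrix cells, fell from 68 tags to 8, a log2 ratio of -2.95 (-4.29 to -1.96). Of 12 measured Hedgehog pathway genes 0 rose and 2 fell, and of 22 Wnt pathway genes 0 rose and 2 fell; both pairs of numbers were the same when adjusted over the list alone. The second Hedgehog gene was Hhip, a Hedgehog inhibitor, at -2.30. Wif1, a secreted Wnt inhibitor, fell by 1.90 on the log2 scale and Znrf3, a ligase that removes Wnt receptors, fell by 1.35. Structural genes of the hair, in contrast, were mostly above day 0. The median ratio was 0.82 (0.23 to 0.97) for 13 hair shaft keratins, 0.50 (0.15 to 0.75) for 44 keratin-associated proteins and 0.45 (0.30 to 0.60) for 16 inner root sheath genes, the tube that guides the growing shaft. Of these 1, 4 and 1 rose and 0 fell, and the counts were 1, 4 and 1 when adjusted over the list alone. Krt32 of the shaft rose by 1.28 (1.20 to 1.37) and Krt72 of the sheath by 1.15 (0.88 to 1.43). The keratin-associated proteins were Krtap12-1 at 1.48 (1.36 to 1.60), Krtap16-3, Krtap7-1, not called by tags that match 1 reference gene exactly (exact tags, 0.59), and Krtap4-6, not called when scaled by tags assigned to genes (0.98). Of 20 melanogenesis genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), namely Gpr143, a receptor of melanosomes, at 1.63 (1.20 to 2.08), the transporter Slc45a2 at 1.25 and the melanosome fibre protein Pmel at 1.22. Among 28 hair matrix regulators 2 rose and 1 fell, here too the same when adjusted over the list alone. Gprc5d rose by 1.12, though it was not called when scaled by tags assigned to genes (0.99). Bmp7, a growth factor, was at 1.01, but at -0.40 by exact tags and not called under 3 other scalings, and the 1 that fell was Shh.

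Other tissue components also differed between these libraries. Skeletal muscle genes, which whole skin holds through the muscle sheet under the dermis, had a median of 0.66 (0.41 to 0.88). Of 25 measured 5 rose, 5 when adjusted over the list alone. They were Myh4, a fast myosin heavy chain, at 1.91 (1.20 to 2.73), the oxygen store Mb at 1.01, and Actn3, Tnnt3 and Myh2, and under 3 other scalings the last 4 were under 2-fold. Tnnt3 stood at -0.49 at its 3'-most site, which held 0.8% of its tags. Of 15 stress epidermal genes, 3 rose and 0 fell, also when adjusted over the list alone: S100a9, a calcium-binding protein of inflamed epidermis, at 1.54, Krt16 at 1.40 and Sprr1b at 1.02, the last not called under 3 other scalings. For 14 macrophage and monocyte genes the median was 0.23 (-0.48 to 0.51). There 1 rose, also when adjusted over the list alone, namely Fcgr1 at 1.47, which was not called by its exact tags (1.38) or under 2 other scalings. Cytosolic ribosomal proteins had a median of -0.30 (-0.56 to -0.07), and of 39 measured 5 fell, 5 when adjusted over the list alone. Rpl15 fell by 2.07, Rpl5 fell by 1.92, Rps27l fell by 1.12 and Rpl9 fell by 1.09. Rpl32, at -3.38 (-4.11 to -2.78), rested on a tag in coding exon 3 of 4 with 244 copies at day 0 and 20 at day 1.

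Genes of cell division were not called at day 1. Of 30 proliferation genes and 30 DNA replication genes the count was 0, over all genes and when adjusted over the list alone, and their medians were -0.22 (-0.44 to 0.12) and -0.05 (-0.29 to 0.10). Mki67, a marker of cycling cells, was at -0.55 (-0.85 to -0.25) and Top2a, the topoisomerase of dividing cells, at -0.46 (-1.01 to 0.08). Of the proliferation ratios 10 were positive and 20 negative, the median lying at percentile 2.8 of random lists. Of the DNA replication ratios 14 were positive and 16 negative. Plk1 stood at 0.85 (0.42 to 1.30) and Rrm2 at 1.00 (0.49 to 1.53), but Nusap1 at -0.92 (-1.34 to -0.52). Single calls appeared in other settings. Nusap1 fell when scaled by tags assigned to genes (-1.05), Rrm2 rose under DESeq2 size factors (1.01) and Mcm3 at its 3'-most site (1.03).

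In all, 199 clusters rose and 187 fell at day 1, of 13812. Scaling by all kept tags gave 156 higher and 265 lower, by tags assigned to genes 128 and 338, and by such tags outside hair and muscle genes 149 and 283, so the balance of directions depended on the scaling. A further count came from edgeR's exact test with an assumed coefficient of variation between animals (the assumed-variation test). It used an adjusted p of 0.05 without a fold minimum. At a coefficient of 0.2 it gave 16 higher and 13 lower, and at 0.4 it gave 0 and 0.

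The day 2 and day 0 libraries extend the question to 2 days after the drug. Macrophage genes and single chemokine genes were higher at day 2. Of 14 macrophage and monocyte genes 8 rose and 0 fell (8 adjusted over the list alone), with a median of 1.24 (0.34 to 1.91), and their summed level went from 453 to 1022 CPM. Fcgr1, an antibody receptor, rose by 2.17 (1.49 to 2.98), Ms4a7 by 1.93 (1.49 to 2.42) and the mannose receptor Mrc1 by 1.57 (1.31 to 1.84). Of 19 inflammatory cytokine and chemokine genes 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.52 (-0.07 to 1.35). The monocyte-attracting chemokine Ccl2 rose from 4 to 88 tags (4.34, 3.10 to 6.41), the alarmin Il33 by 2.55 (1.90 to 3.32), Ccl7 by 2.10 (1.65 to 2.61) and Ccl8 by 1.13. The 1 that fell was Nfkbia, an inhibitor of NF-kB, at -1.08. The related Ccl12 rose by 4.74 (3.82 to 6.06) and Cxcl13, which attracts B cells, by 4.21 (3.07 to 5.99).

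Haemoglobin genes stood at the other end. The alpha globin cluster whose tags occur in both Hba-a1 and Hba-a2 fell from 4942 tags to 361, a log2 ratio of -3.73 (-3.89 to -3.57); the tags cannot separate these gene copies. Of 7 measured erythroid genes 5 fell and 0 rose (5 and 0 adjusted over the list alone), and their summed level went from 1954 to 215 CPM (-3.18, -3.31 to -3.06). Alas2, the first enzyme of haem synthesis in red cells, fell by 2.17 on the log2 scale. The other members that fell were Hba-a1 at -3.05, the beta globin cluster of Hbb-bs/Hbb-bt at -2.98 and Hba-a2, with 30 tags at day 0 and no listing at day 2.

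Among follicle genes, those of the inner root sheath had a median of -0.47 (-0.94 to -0.05) at day 2. Of 16 measured 2 fell and 0 rose, with the same numbers when adjusted over the list alone. These were Gata3, a transcription factor of the sheath, at -1.07 (-1.22 to -0.92) and Krt25 at -1.04 (-1.07 to -1.02). Neither call held in every setting, with Gata3 at -0.63 at its 3'-most site and Krt25 at -0.98 when hair and muscle genes were left out of the scaling. Hair shaft keratins had a median of 0.22 (-0.50 to 0.92), and 2 of 13 fell, also when adjusted over the list alone. Krt35, a keratin of the early shaft, fell by 2.09 and Krt36 fell by 1.33. Of 28 hair matrix regulators 5 fell and 0 rose (5 adjusted over the list alone), namely Shh, the Wnt ligand Wnt10b at -2.40, and the transcription factors Nfil3 at -1.71, Dlx4 at -1.56 and Msx2 at -1.14. The median of 22 Wnt pathway genes was -0.31 (-1.48 to 0.19), and 5 fell and 0 rose (5 adjusted over the list alone). Wif1 fell by 2.94, Wnt11, a Wnt ligand, fell by 1.82, the Wnt inhibitor Nkd2 fell by 1.58 and Znrf3 fell by 1.48, besides Wnt10b. Among 12 Hedgehog genes 1 rose and 2 fell, the same when adjusted over the list alone. Shh fell by 2.19, Hhip fell by 2.11 and Gas1, a Hedgehog co-receptor, rose by 1.11, though it was not called at its 3'-most site (0.96). In 44 keratin-associated proteins, by contrast, 5 rose and 1 fell, also when adjusted over the list alone, with a median of 0.51 (0.33 to 0.72). Krtap4-2 rose by 1.31, Krtap1-3 by 1.29, Krtap4-6 by 1.27 and Krtap16-3 by 1.04, the last of the 5 being Krtap7-1, not called by its exact tags (0.16), and Krtap19-1 fell by 1.15. Of 20 melanogenesis genes 1 rose and 1 fell, the same when adjusted over the list alone, namely Pmel at 1.55, whose second site had 44 tags at day 0 and 31 at day 2 (-0.45), and the pigment cell regulator Mitf at -1.17.

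Of 34 p53 target genes 7 rose and 0 fell (8 adjusted over the list alone), with a median of 0.28 (-0.19 to 0.82). Their ratios were positive in 20 and negative in 14. Ccng1, cyclin G1, rose from 11.02 to 42.98 CPM (1.95, 1.38 to 2.58), Ephx1 by 1.49 and Gtse1, which restrains p53, by 1.45. Tnfrsf10b stood at 1.29 and was not called at its 3'-most site (0.96) or by its exact tags (0.99). Cdkn1a and Mdm2 were again not called, at -0.04 (-0.47 to 0.38) and 0.02 (-0.35 to 0.40). Mgmt again rose, by 3.88 (2.73 to 5.67), the 1 DNA repair gene of 31 to do so, also when adjusted over the list alone. Of 18 interferon-stimulated genes 3 rose and 0 fell (3 adjusted over the list alone), with a median of 0.64 (0.37 to 1.03). Among them were Ifit3 at 1.87 and Bst2 at 1.85. Rrm2, a subunit of ribonucleotide reductase, was the 1 of 30 DNA replication genes that rose, at 1.07, with the same count when adjusted over the list alone. Of 30 proliferation genes none was called over all genes or when adjusted over the list alone, with a median of -0.02 (-0.16 to 0.14).

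Skeletal muscle genes were higher again. Of 25 measured 10 rose and 0 fell (11 adjusted over the list alone), with a median of 0.96 (0.73 to 1.27). Actn3, a protein of fast fibres, rose by 1.93, Mb by 1.43 and Mylpf, a myosin light chain, by 1.35. Outside that list, Ankrd1, an ankyrin repeat protein of stressed muscle, rose from 2 tags to 396 (7.35, 5.81 to 10.73). Of these 377 were CATGTAGGGAGATGGAGGGAG, in the 3' UTR on chromosome 19 (36112094 to 36112114). Myog, a transcription factor of muscle formation, rose from 2 tags to 57 (4.57, 2.96 to 7.96), while Apobec2, a deaminase relative of muscle, fell from 413 tags to 33 (-3.58, -4.16 to -3.09). Dermal fibroblast matrix genes had a median of 0.50 (0.37 to 0.69), and of 25 measured 3 rose (3 adjusted over the list alone). They were Loxl1, which cross-links elastin, at 1.33, the fibroblast receptor Pdgfra at 1.31 and the proteoglycan Lum at 1.16. Of the 25 ratios 21 were positive and 4 negative. The list's summed level changed less, from 12268 to 13565 CPM (0.14, 0.12 to 0.17), and the collagen gene Col1a2 went from 1487.3 to 1090.2 CPM. Cytosolic ribosomal proteins had a median of -0.55 (-0.67 to -0.23), and of 39 measured 7 fell and 0 rose (8 adjusted over the list alone). Further genes with large falls were the homeobox genes Hoxb8 at -3.75 (-5.34 to -2.68) and Barx2 at -3.33 (-3.93 to -2.82), and Selenbp1, a selenium-binding protein, at -3.05 (-3.40 to -2.73).

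At day 2, 471 clusters rose and 419 fell against day 0. The assumed-variation test gave 146 and 95 at 0.2, and 5 and 1 at 0.4.

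**Figure D1:**
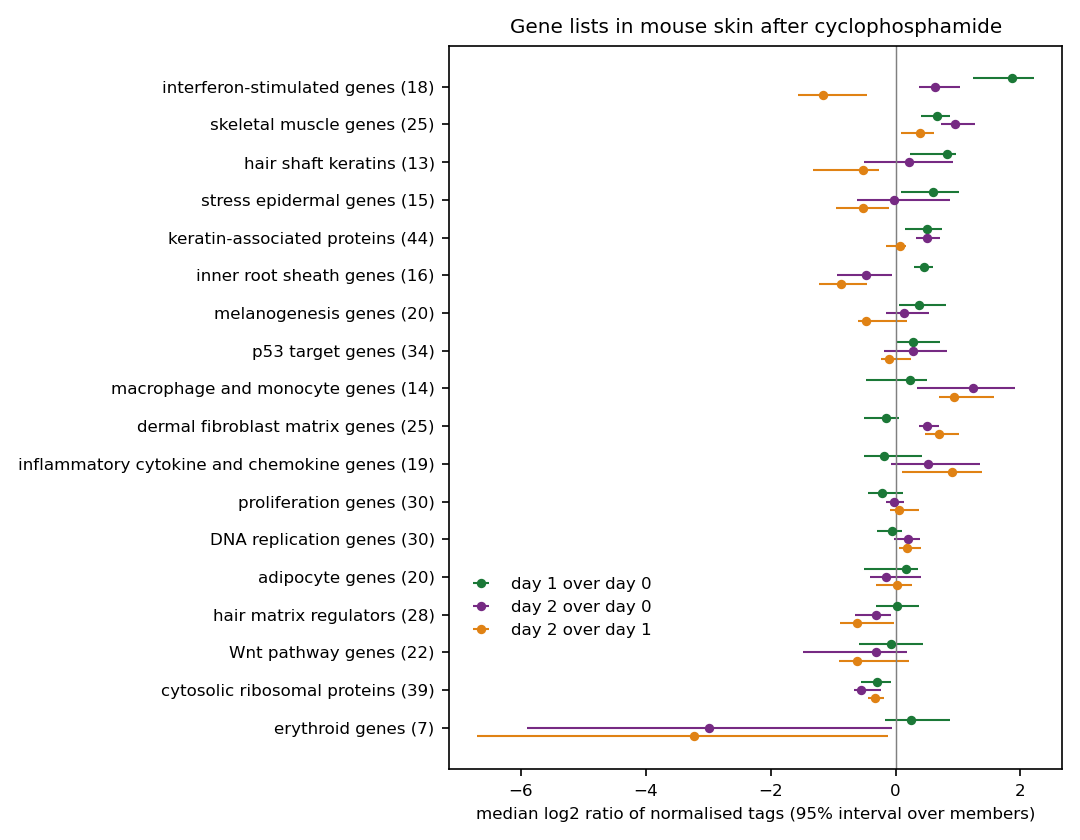
Median log2 ratio of normalised tags (horizontal axis) of 18 gene lists fixed beforehand, with the number of measured members in parentheses. Points are medians and bars 95% intervals over members, in green for day 1 over day 0, purple for day 2 over day 0 and orange for day 2 over day 1. Interferon-stimulated genes stand highest at day 1 over day 0, at 1.87, and erythroid genes lowest at day 2. The low ends of the long erythroid bars come from 1 gene, Hba-a2, that was not listed at day 2 and entered as 0 tags with the pseudocount, so they are not measured bounds. Points near 0, such as stress epidermal genes at -0.02 or hair matrix regulators at 0.02, change sign with the scaling.

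The day 2 and day 1 libraries show what differed between the first and the second day after the drug. Interferon-stimulated genes were lower at day 2 than at day 1. Of 18 measured 5 fell and 0 rose (6 adjusted over the list alone), with a median of -1.16 (-1.57 to -0.46). Isg15 fell by 1.97 and Ifit3 fell by 1.57, while Ifit1 at -2.17 was not called at its 3'-most site (-1.43), and Ifih1 at -1.22 not when hair and muscle genes were left out of the scaling (-1.07). The last of the 5 was Ifit2 at -1.97. Cmpk2, an interferon-induced nucleotide kinase outside the list, fell by 2.62.

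Inner root sheath genes were lower too. Of 16 measured 8 fell and 0 rose (8 adjusted over the list alone), with a median of -0.87 (-1.23 to -0.46), and their summed level went from 66086 to 27276 CPM. Krt25 fell from 23654.3 to 7891.4 CPM, a log2 ratio of -1.58 (-1.61 to -1.56). Krt27 fell by 1.54, Padi3, an enzyme that modifies sheath proteins, fell by 1.39 and Krt73 fell by 1.23, while Krt71 at -1.02 was not called under 3 other scalings or by its exact tags. Hair shaft keratins had a median of -0.52 (-1.32 to -0.27), and of 13 measured 3 fell (3 adjusted over the list alone), with Krt35 at -1.63, Krt36 at -1.57 and Krt87 at -1.32. The median of 28 hair matrix regulators was -0.61 (-0.89 to -0.03), and 3 fell and 0 rose (4 adjusted over the list alone). Nfil3 fell by 1.44, and Ovol1 at -1.12 and Cux1 at -1.03 were not called under some other scalings. In 22 Wnt pathway genes 1 rose and 3 fell, the same when adjusted over the list alone, with Wnt11 at -1.23, Nkd2 at -1.21 and Wnt3 at -1.05 lower, the last not called under 3 other scalings, and the inhibitor Dkk2 at 2.10 higher. The keratin-associated proteins had a median of 0.07 (-0.15 to 0.17), and of 44 measured 1 rose and 1 fell, the same when adjusted over the list alone. Krtap1-3 rose by 1.52, and the 1 that fell, Krtap10-4 at -1.29, stood at 0.15 by its exact tags.

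Genes of macrophages, chemokines and the dermal matrix were higher at day 2 than at day 1. Of 14 macrophage and monocyte genes 5 rose and 0 fell (5 adjusted over the list alone), with a median of 0.94 (0.70 to 1.57). Mrc1 rose by 1.77, Ms4a7 by 1.57, Fcer1g, the signalling chain of Fc receptors, by 1.28 and the lysozyme Lyz2 by 1.19. The chemokine receptor Ccr2, at 1.25, was not called at its 3'-most site (1.05). The macrophage receptors Msr1 and Trem2, outside that list, rose by 3.63 (2.35 to 5.71) and 3.36 (2.27 to 4.96). Of 19 cytokine and chemokine genes, with a median of 0.91 (0.10 to 1.38), 4 rose and 0 fell (4 adjusted over the list alone), with Ccl2 at 2.70, Il33 at 2.42, Ccl7 at 2.23 and Ccl8 at 1.32. Of 25 dermal fibroblast matrix genes 5 rose and 0 fell (7 adjusted over the list alone), with a median of 0.70 (0.47 to 1.01). Lum rose by 1.57, Lox, a collagen cross-linking enzyme, by 1.32 and the proteoglycan Dcn by 1.13. Thbs2 at 1.29 and Loxl1 at 1.25 were not called at their 3'-most sites (1.01 and 1.25). At day 1 over day 0 this matrix list had a median of -0.16 (-0.50 to 0.06), with 0 called (1 lower adjusted over the list alone). Its summed level was 12268, 10246 and 13565 CPM at days 0, 1 and 2, so it was lowest at day 1. Skeletal muscle genes had a median of 0.39 (0.09 to 0.62), and of 25 measured 2 rose (2 adjusted over the list alone), Ampd1 at 1.29 and Neb at 1.18. Outside that list single genes known from muscle went both ways. Mybph was at 4.00 (2.58 to 6.53), the cardiac actin Actc1 at 3.60 (2.43 to 5.40) and Ankrd23 at 3.03 (2.62 to 3.49), while Apobec2 fell by 2.63 on the log2 scale (-3.22 to -2.11). Ankrd1 and Myog were called higher but were not listed at day 1, so no fold is given. Of 7 erythroid genes 6 fell and 0 rose (6 adjusted over the list alone), with the alpha globin cluster of Hba-a1/Hba-a2 at -3.55 (-3.71 to -3.40).

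Between day 1 and day 2, 249 clusters rose and 152 fell. Scaling by all kept tags gave 347 and 106, by tags assigned to genes 371 and 100, and by such tags outside hair and muscle genes 389 and 92. The assumed-variation test gave 57 and 33 at 0.2, and 2 and 0 at 0.4.

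**Figure D2:**
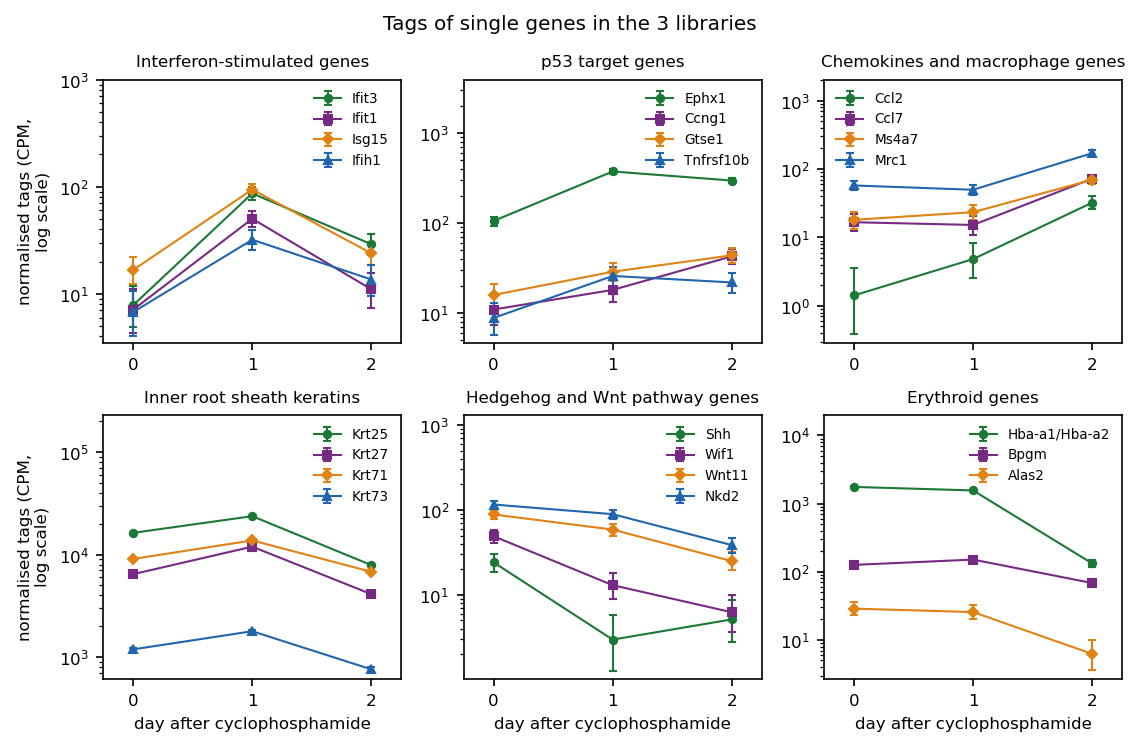
Normalised CPM (vertical axis, log scale) of single genes against the day after cyclophosphamide (0, 1 and 2), 1 library per day, in 6 panels of related genes. Bars are exact 95% Poisson intervals of the counts, many smaller than the symbols, and cover counting error only. Ifit3 peaks at day 1 at 86.63 CPM, the sheath keratin Krt25 falls to 7891.4 at day 2, and Ccl2 reaches 32.32 at day 2 from 1.42 at day 0.

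The calls of both treated libraries against day 0 were also compared with each other. Of the clusters, 96 rose at both days and 98 fell at both, against 6.8 and 5.7 for independent lists of those sizes. A single cluster, Aspn, an extracellular matrix protein named here after its values were seen, fell at day 1 and rose at day 2. The log2 ratios of both comparisons had the same sign in 70.6% of 13812 clusters, against 66.5% (65.7 to 67.4) in 100 simulations of unchanged libraries against the same day 0 library. Across genes, which are not independent replicates, Pearson's r was 0.56 against a simulated 0.49, and the covariance was 0.35 against 0.09, a difference of 0.26. Day 0 is 1 library and cannot be split, so part of the overlap beyond independent lists may come from sharing it.

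Members named only to complete a count of 5 or fewer, such as Hhip, Wnt10b, Dkk2, Nfkbia, Lyz2 and Dcn, were chosen after their values were seen.

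Some genes fixed for naming were poorly covered in the tables, which hold 45.3% to 47.1% of the kept tags. Trp53, Lef1, Krt85 and Fos were not measured. For Krt14 and Krt1, main keratins of basal and differentiating epidermis, 0.0% of tags lay at the 3'-most site, and 231 and 15 tags at day 0 came from other sites. Whether tags of their main sites were absent from the libraries or left out of the tables is not given in the sources used here, so these counts do not measure the level of either gene. Other genes named above, such as Fcgr1 and Rrm2, also had 0.0% of tags at the 3'-most site. Their ratios rest on other sites, and their levels carry the same doubt. The genes with the most tags in a library included Rplp1 (49800 at day 0), Krt25 (45778), Prr9 (26336), Krt71 (25497) and Sparc (24125).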

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

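The tests of immune cells, of the follicle share and of erythroid genes other than haemoglobins, and all readings of tags without a match and of Aspn, were chosen only after the result was seen, and the exact-tag counts used for related keratins were added then too.

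Between the treated libraries themselves, 249 clusters were called higher at day 2 than at day 1 and 152 lower, so the 2 days after the drug differed in a direct test of their reads. With 1 library per day this separates 2 libraries and does not separate the day from the animal. Aspn, which encodes asporin, a small proteoglycan that binds collagen, stood out as the 1 cluster called in opposite directions against day 0. It had 178, 51 and 369 tags at days 0, 1 and 2, with log2 ratios of -1.73 at day 1 over day 0, 1.10 at day 2 over day 0 and 2.83 at day 2 over day 1. Tags without a match in the reference transcripts counted within their clusters in every comparison, except where exact tags were used. Such tags were above their day 0 share of 4.00% (3.97 to 4.02) at both treated days, with 5.08% (5.05 to 5.10) at day 1 and 5.86% (5.83 to 5.89) at day 2. How much they added to the ratios of single genes was not tested. Those ending in 8 or more A, as a tag does that runs into the poly(A) tail, made up 1.48%, 2.45% and 3.06% of the libraries. The others made up 2.51%, 2.63% and 2.80%, and tags 1 base away from a tag 10 times as abundant, as sequencing errors would be, 0.55%, 0.64% and 0.60%.

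The interferon-stimulated genes at day 1 over day 0 (median 1.87, 1.24 to 2.22) were weighed against a larger number of immune cells in the day 1 piece of skin. Such cells bring their own transcripts, yet the macrophage and monocyte genes had a median of 0.23 (-0.48 to 0.51), below the lower end for the interferon-stimulated genes. The 8 lymphocyte genes had a median of 0.19 (-1.52 to 0.83). These medians argue against a rise of such cells as large as that of the interferon-stimulated genes. They cannot exclude fewer added cells rich in interferon-stimulated transcripts. Those genes started lower, at 175 CPM summed at day 0 against 453 for the macrophage and monocyte genes. An interferon response of cells already in the skin stays open as a hypothesis, as do the drug, a further day of hair growth and differences between animals, which 1 library per group cannot separate. None of these was tested.

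The inner root sheath genes at day 2 over day 1 (median -0.87, -1.23 to -0.46) were weighed against a smaller share of follicles and against tags shared between related keratins. Keratin-associated proteins of the shaft, from the same follicles, had a median of 0.07 (-0.15 to 0.17), above the upper end for the sheath. If their level per follicle was steady, this argues against a smaller follicle share as the whole cause. A rise per follicle from day 1 to day 2 could hide a smaller share, and these counts cannot show it. Some other follicle lists were lower too, with medians of -0.52 (-1.32 to -0.27) for hair shaft keratins and -0.61 (-0.89 to -0.03) for hair matrix regulators. Melanogenesis genes stood at -0.48 (-0.60 to 0.18). Outer root sheath and companion layer keratins were nearer 0, at -0.17 (-1.60 to 0.17), as were dermal papilla genes, at -0.06 (-0.62 to 0.35). The follicle lists thus did not move together, and a smaller share as part of the cause stays open. By exact tags the 16 sheath genes had a median of -0.85 (-1.26 to -0.45), below 0, and the median met the bound of -0.5 set for it. This argues against shared tags as the whole cause, though exact-tag counting itself was added after the data were seen. A change in sheath cells after the drug, a further day of hair growth and the stage of each animal's follicles stay open and were not tested.

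The erythroid genes at day 2 over day 0 were weighed against less blood in the day 2 piece of skin and against a change in how haemoglobin tags were assigned. The summed tags of 3 erythroid genes other than haemoglobins gave -1.01 (-1.25 to -0.77), which argues against the assignment of haemoglobin tags as the whole cause but leaves open how much it adds to the larger haemoglobin fall. Bpgm, with 355 tags at day 0 and 186 at day 2, weighed more in this sum than Alas2, with 81 and 17, so the sum hides unlike falls. Summed tags of 5 platelet genes measured out of 12 (173, 127 and 188 tags) gave 0.17 (-0.14 to 0.47), far above the bound of -2 set beforehand. That bound was wrong for these genes, because Pf4 (123, 63 and 140 tags) and Itga2b (37, 55 and 29) are also made by macrophages and mast cells, whose own genes were higher at day 2; without them 13, 9 and 19 tags remain (0.59, -0.50 to 1.73), too few to decide. Less blood in the sample, fewer young red cells after the drug, and differences between animals therefore cannot be told apart.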

How the results depend on the processing

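Counting exact tags of 1 reference gene was the 1 alternative among these tests chosen only after the result was seen. It replaced a planned match with 1 mismatch, which was not run because the tables already hold near matches. A planned minimum of 2 copies per tag was not run either, since the tables hold no lower copy number. No paired analysis was possible because every group has 1 library, numbered replicate 1.

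Counts of called clusters stayed within 1.5 times the reported ones under DESeq2 size factors, scaling by all kept tags, filters of 1 and 60 tags, the 3'-most site alone and exact tags, which gave 156 to 217 higher and 168 to 265 lower at day 1 over day 0. Scaling by tags assigned to genes gave 128 higher and 338 lower at day 1 over day 0 and 100 lower at day 2 over day 1. Leaving hair and muscle genes out of that scaling gave 283 lower at day 1 over day 0, and 389 higher and 92 lower at day 2 over day 1. These scalings move the median of all clusters, reported at -0.02 for day 1 over day 0 and -0.02 for day 2 over day 1, to -0.15 and 0.12, and to -0.11 and 0.14. Scaling by all kept tags moved it to -0.09 and 0.10. The counts move with that shift.

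Without a fold minimum the calls were 808 higher and 702 lower (day 1 over day 0), 1002 and 1084 (day 2 over day 0) and 629 and 724 (day 2 over day 1), with 399 higher and 456 lower at both days against day 0. At a minimum of 4-fold they were 28 and 17, 110 and 57, and 64 and 27, with 14 and 7 at both days. edgeR's exact test with an assumed coefficient of variation of 0.2, an adjusted p of 0.05 in place of 0.001 and no fold minimum, 3 choices changed together, gave 16 and 13, 146 and 95, and 57 and 33, with 10 and 6 at both days; one of 0.4 gave 0 and 0, 5 and 1, and 2 and 0, with 0 and 0. For the fold minimum the wider or narrower criterion is itself the cause; for the assumed variation, the share of each choice was not tested. The true variation between animals is not known here.

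Of 123 list medians, those that left their interval belonged to 3 lists. Oxidative phosphorylation genes at day 1 over day 0 (0.07 as reported) went to -0.06 by tags assigned to genes and -0.02 without hair and muscle genes. At day 2 over day 1 (-0.26) they went to -0.14 by all kept tags, -0.13 by assigned tags and -0.11 without hair and muscle. Keratin-associated proteins at day 2 over day 1 (0.07) went to 0.19, 0.20 and 0.22 in the same order. All follow the shift given above. Cytosolic ribosomal proteins at day 2 over day 1 (-0.33) went to -0.17 without hair and muscle genes and to -0.17 by exact tags; for the latter the cause was not tested.

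Among named genes 4 values reversed in sign. By exact tags Bmp7 at day 1 over day 0 was -0.40 and Krtap10-4 at day 2 over day 1 was 0.15. At the 3'-most site Tnnt3, with 0.8% of its tags there, was -0.49 at day 1 over day 0 and Cdkn1a was 2.22. The cause was not tested. Of the values of named genes, 563 kept their direction and side of the threshold under DESeq2 size factors, 3 became called and 1 lost its call; the numbers were 552, 7 and 8 by all kept tags, 541, 14 and 12 by assigned tags, and 536, 17 and 14 without hair and muscle genes. At the 3'-most site they were 406, 27 and 12, and by exact tags 539, 4 and 6. Named genes not tested in those settings, for example for too few tags, were left out there. Both settings, and the 3'-most site above all, thus cover fewer values than the scalings do. A pseudocount of 5 ended 8 calls, and the test with an assumed variation ended 103 at 0.2 and 187 at 0.4.

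Antisense tags were 3.0%, 2.42% and 2.54% of the libraries and 2.09%, 1.80% and 1.94% counting those of 1 gene. Adding tags shared within the list took the exact tags of hair shaft keratins from 8064, 12859 and 8486 CPM to 8109, 12963 and 8571. Keratin-associated proteins had 0 such shared tags. Their exact tags gave 51840, 67738 and 67181 CPM, against 60446, 82092 and 81495 as reported by cluster. The log2 ratios of this total against day 0 then fell below their intervals, 0.43 to 0.45 at day 1 and 0.42 to 0.44 at day 2. Depth limits genes below 20 CPM most, as the simulated data showed.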

Other observations

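The values in this part come from lists fixed beforehand, while the tests that compare CATG sites of 1 gene were chosen only after the result was seen, as were the names of genes below 20 CPM.

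Several cell types of the skin beside the follicle showed single called genes. For 9 mast cell genes the median at day 2 over day 0 was 0.67 (0.35 to 1.47), and 2 rose, the high-affinity IgE receptor chain Fcer1a at 2.20 and the protease Cpa3 at 1.03, the latter not called at its 3'-most site (0.91) or with a pseudocount of 5 (0.98). At day 2 over day 1, 2 rose (3 adjusted over the list alone), Cma1 at 1.03 and Cpa3 at 1.04. Neither was called with a pseudocount of 5 (0.99 and 0.98), nor Cpa3 at its 3'-most site (0.76). For 14 endothelial genes the median at day 2 over day 0 was 0.73 (0.14 to 1.07). There Vwf, the platelet-binding factor of vessel walls, rose by 1.38 and the receptor Tie1 by 1.60, while Egfl7 stood at -1.06 and was not called when scaled by tags assigned to genes outside hair and muscle (-0.99). Of 8 lymphocyte genes 2 rose at day 2 over day 0, Ptprc, the common leukocyte antigen, at 1.28 and Thy1 at 1.14. The list as a whole did not, with a median of 0.15 (-0.59 to 1.28) and 4 ratios positive and 4 negative. Thy1 held 295.0 of the list's 352 CPM at day 2. At day 2 over day 1 Ptprc rose by 2.15. Of 8 antigen-presenting cell genes 1 was called, H2-Ab1, a chain of MHC class II, which rose by 1.18 at day 2 over day 1. Of 12 nerve and Schwann cell genes 1 was called, the sodium channel Scn7a, from 4 to 24 tags (2.49) at day 2 over day 0. Only 3 neutrophil genes were measured, and 0 were called in any comparison.

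Lipid genes moved apart. In 18 sebaceous gland genes Fads2, a fatty acid desaturase, fell by 2.29 at day 2 over day 0 (259, 122 and 51 tags at days 0, 1 and 2) and Dgat2, which makes triglycerides, fell by 1.91, while Dgat2l6, a wax synthase relative, rose by 1.16. At day 1 over day 0 Fads2 at -1.02 and Scd3 at -1.01 were called, but not with a pseudocount of 5 (-0.99 and -0.99), nor Scd3 under DESeq2 size factors. At day 2 over day 1 Fads2 fell by 1.27 and Dgat2 fell by 1.45, while 13 of the 18 ratios were positive. The median was 0.43 (-0.17 to 0.69), at percentile 100 of the random lists, and the summed level went from 2622 to 3653 CPM. In 20 adipocyte genes the hormone gene Lep rose by 1.66 at day 2 over day 0 and Nnat, with 41, 45 and 4 tags at days 0, 1 and 2, fell at day 2 over both other days. The adipocyte list's summed level went from 6120 to 4436 CPM at day 2 over day 0 (-0.46, -0.50 to -0.43), with 8 ratios positive and 12 negative. Fabp4 had 9414 tags at day 0 and 4649 at day 2, and was called lower at its 3'-most site (-1.02). In 20 lipid synthesis genes Idi1, of the sterol pathway, fell by 1.08 at day 1 over day 0, and Elovl6 at 1.09 at day 2 over day 1 was not called at its 3'-most site (0.83).

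Early response genes did not move together. Ier2 fell by 1.48 at day 1 over day 0 and fell by 1.66 at day 2 over day 0, Ier3 fell by 1.88 at day 2 over day 0 and fell by 2.38 at day 2 over day 1, and the nuclear receptor Nr4a1 rose by 1.75 at day 2 over day 0. Of 17 circadian clock genes Tef rose by 1.07 at day 2 over day 0, and Per3 at 1.07 at day 2 over day 1 was not called with a pseudocount of 5 (1.00). Of 11 glucocorticoid-responsive genes Map3k6 fell by 1.09 at day 2 over day 0 and fell by 1.41 at day 2 over day 1. The antiapoptotic gene Bcl2 was the 1 called of 23 apoptosis regulators, at 1.35 at day 2 over day 0, but not at its 3'-most site (1.01). Of 22 NRF2 and detoxification genes 1 was called, Ephx1, at both days against day 0.

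In the follicle and epidermis, 8 outer root sheath and companion layer keratins had a median of 0.74 (0.08 to 1.40) at day 1 over day 0, where Krt16 rose by 1.40, and Krt16 rose by 1.22 at day 2 over day 0. In 19 dermal papilla genes Wif1 fell at both days against day 0 and Lepr fell by 2.52 at day 2 over day 0. At day 2 over day 1 Vcan, a matrix proteoglycan, rose by 1.21, and Fgf7 was called higher with 9 tags at day 0, no listing at day 1 and 15 tags at day 2, so no fold is given. In 29 interfollicular differentiation genes, 0 were called against day 0 (1 at day 1 when adjusted over the list alone). At day 2 over day 1 Tgm1, which cross-links the cornified envelope, fell by 1.34, Dsc1 of desmosomes fell by 1.23 and Krt2 rose by 2.27. Of 15 catagen-associated genes 0 were called in all 3 comparisons, and of 13 endoplasmic reticulum stress genes also 0. The catagen-associated median was 0.45 (-0.13 to 0.61) at day 2 over day 1, at percentile 99.5 of random lists. For endoplasmic reticulum stress genes it was 0.32 (0.06 to 0.75) at day 1 over day 0, at percentile 97.2, with 11 ratios positive and 2 negative. Of 26 oxidative phosphorylation genes Ndufv1, of complex I, fell by 1.10 at day 2 over day 0. Of 14 glycolysis genes Aldoc fell by 1.79 at day 2 over day 0, and of 9 mitochondrially encoded genes mt-Rnr2, a ribosomal RNA, fell by 1.11 at day 1 and fell by 1.30 at day 2 against day 0.

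Genes with 2 CATG sites of 50 or more tags each allow a check within the assay. For day 1 over day 0, day 2 over day 0 and day 2 over day 1 there were 1380, 1391 and 1347 such genes. Across these genes the log2 ratios of both sites had a Pearson's r of 0.22, 0.32 and 0.45, and a median absolute difference of 0.47, 0.49 and 0.34. Where the main site differed by 2-fold or more (96, 152 and 82 genes), the second site had the same sign in 70, 118 and 63 (72.9%, 77.6% and 76.8%). Sites differed by 4-fold or more in 8, 14 and 3 genes. In the intermediate filament gene Vim, the tag CATGAAGGAAGAGATGGCTCG on chromosome 2 (13580122 to 13580142), in coding exon 6 of 9, had 1402, 89 and 826 copies at days 0, 1 and 2. The next site upstream, CATGTCCAGATCGATGTGGAC in exon 4, had 54, 66 and 73. The fall of Vim by 2.84 at day 1 over day 0 thus rested on 1 site. In Cdkn1a, CATGGCGGGCTGTCTCCAGGA on chromosome 17 (29098515 to 29098535), in coding exon 2 of 3, had 88, 50 and 73 copies, while the 3' UTR tag CATGTATTGTGGCTCCCTCCC in exon 3 had 5, 24 and 7. The whole-gene ratio near 0 at day 1 thus joins sites that moved in opposite ways, and no test here shows which of them follows the transcript. Ppm1a, a phosphatase at 2.87 at day 2 over day 1, stood at 0.89 by exact tags.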
